A study of Mus musculus with 12 samples.

How the data were processed

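RNA of brown adipose tissue from male wild-type (WT) and Zbtb7b knockout (KO) mice, 10 weeks old and kept at 22 °C or at 4 °C for 4 h, was measured on 12 whole-transcript arrays. Per the labels, biotin-labelled cDNA was made from 400 ng of total RNA, and the tools named were oligo, RMA and limma, with no versions or array parameters stated. The deposited values are log2 signals made by the authors with RMA, which corrects the background, brings the arrays to the same distribution and summarises the probes of a probe set. The scale is not written with the values, and the range and the near-equal quartiles of the 12 arrays were checked against it. The raw scans were not used here. For arrays only their number limits the precision, which was 3 per group.

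Groups were taken from the titles, source and characteristics, which name brown fat, genotype and temperature. The description field of the same labels names liver and another knockout, so a hepatocyte list was included as a check of the tissue. The numbers in the titles were not taken as pairs. Of 41345 probe sets, 23521 carried exactly 1 gene symbol and were used, 1814 carried several and 16010 carried none. For the 1082 genes with several probe sets the brightest over all 12 arrays was kept, which left 22180 genes, with no filter on low signal.

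In R 4.3.3 with limma 3.58.1, a linear model with 1 mean per group was fitted to all 12 arrays, with moderated spread (eBayes). It gave 7 comparisons, namely KO against WT at room temperature, in the cold and over both, cold against room temperature in WT, in KO and over both, and the genotype by temperature interaction. Each test was two-sided, p-values were adjusted by Benjamini-Hochberg over all genes within a comparison, and an adjusted p under 0.05 counted as passed. Over the genes that passed in the averaged cold comparison, the interaction was signed by the direction of the cold response and tested with fry.

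Of 31 gene lists with 617 members in all, 30 were tested with 550 members measured, and the list of genes of the mitochondrial genome was left out because 0 of its members were measured. The lists covered brown adipocyte thermogenic genes, cAMP and immediate-early genes, fatty acid oxidation, fat synthesis, cholesterol synthesis, lipolysis and lipid uptake, glucose uptake and glycolysis, the tricarboxylic acid cycle, nuclear genes of oxidative phosphorylation, branched-chain amino acid breakdown, creatine and calcium cycling, heat shock, endoplasmic reticulum stress and ATF4, the proteasome, the clock, angiogenesis and hypoxia, the interferon response and the cell cycle. Cell type lists covered extracellular matrix, white adipocytes, T cells, B cells, macrophages, neutrophils, endothelium, mural and smooth muscle, skeletal muscle, Schwann cells and nerve, erythroid cells and hepatocytes. Each list was tested with camera at a correlation of 0.01, adjusted over the 30 lists of a comparison, and beside it with camera at an estimated correlation and with fry.

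The groups, comparisons, tests, lists, other settings and the rule for naming genes were set before the data were examined. The rule named Zbtb7b, and in each comparison the 10 genes with the largest rise and the 10 with the largest fall that passed and, for comparisons of 2 groups, did not overlap in any array. Predicted genes, clones, small RNAs, pseudogenes and olfactory and vomeronasal receptors were left out. It also named up to 4 members with the smallest p of each list described, and Ucp1, Dio2, Ppargc1a, Elovl3, Cidea, Prdm16, Ebf2, Fgf21 and Hnrnpu. Olfr519, Flad1, Got2, Cish and the clock genes Dbp, Hlf, Per1 and Ciart fall outside the rule and were chosen after their values were seen.

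The other settings set in this way were every probe set on its own, the mean of a gene's probe sets, genes with a mean log2 signal of at least 5, cyclic loess between arrays, centring of each array on its median, a trended and robust spread, array weights, the replicate number as a block, a change of at least 1.5-fold, the 6 arrays of a comparison alone, and 12 fits that each left out 1 array. In 2 settings chosen after seeing the data, the skeletal muscle list mean per array was added as a covariate, and KO cold replicates 1 and 3 were left out together. The latter leaves 1 KO cold array, which is assumed to vary like the other groups. Counts were also taken for other splits of the arrays, 10 for each comparison of 3 against 3 and 100 relabelings for the averaged comparisons and the interaction. Tested on simulated data with the same layout, the fit recovered 78 of 100 genes changed by 1 on the log2 scale and 98 of 100 changed by 2 at room temperature, with 7 false calls, and 37 and 96 of 100 in the interaction, with 12 false calls. A simulated list shift of 0.5 was recovered, with 0 other calls over the 30 lists. The simulated genes were drawn independently, whereas the genes of a list can be correlated in the data (estimated at 0.956 for skeletal muscle). The simulation therefore does not test false list calls that come from such correlation. Gene order along the chromosomes came from the mouse assembly GRCm38.p6.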

Results

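RNA of brown adipose tissue was measured on whole-transcript arrays in wild-type (WT) mice and in mice with a knockout (KO) of Zbtb7b, a zinc finger transcription factor best known for directing CD4 T cell development. The mice were male and 10 weeks old and were kept either at 22 °C (room temperature) or at 4 °C for 4 h (cold). There were 4 groups of 3 arrays, 12 arrays in all, with values for 22180 genes, and the number of arrays limits the precision. The titles called the arrays of a group biological replicates while another field numbered pools, so how many animals each stands for is unknown and the p-values measure the spread between these samples. The median signal per array lay between 2.63 and 2.83 on the log2 scale, and arrays of the same group correlated across probe sets, which are not independent replicates, at r = 0.970 to 0.985. For genes with a group mean under 4, close to that median signal, log2 differences are given without a fold. Over genes with a mean signal of at least 5, the first principal component held 56.2% of the variance and separated the cold arrays from the room-temperature arrays. One label field named liver and another knockout, while the titles, the source and the other labels named brown fat and Zbtb7b. On every array the brown fat gene Ucp1, which encodes the mitochondrial uncoupling protein, lay between 11.55 and 12.95. The mean of 19 hepatocyte genes lay between 2.62 and 2.86, and albumin (Alb) between 1.20 and 2.75.

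Zbtb7b itself was lower on each of the 6 KO arrays than on each of the 6 WT arrays. At room temperature its log2 signal was 4.47, 4.52 and 4.76 on the WT arrays and 3.62, 3.50 and 3.30 on the KO arrays. In the cold it was 4.36, 4.26 and 4.63 in WT and 2.96, 3.38 and 3.01 in KO. The difference was -1.11 ± 0.16 (SE, n = 3 per group, adjusted p = 0.00904) at room temperature, -1.30 ± 0.16 (adjusted p = 0.00365) in the cold and -1.21 ± 0.11 (adjusted p = 2.91e-04) over both temperatures. The signal was low in WT as well, and whether the probe set lies in the deleted part of the gene is unknown, so these values check the labels and do not measure the loss of the protein. With KO cold replicates 1 and 3 left out together, chosen after seeing the data, 1 KO cold array is left and is assumed to vary like the other groups. The difference of that array in the cold was -1.04 with an adjusted p of 0.129. Zbtb7b did not change with cold in WT by the test (-0.16 ± 0.16, adjusted p = 0.566) or in KO (-0.35 ± 0.16, adjusted p = 0.154).

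The first comparison asked what the knockout changed at room temperature. Dio2, the deiodinase that makes active thyroid hormone in brown fat, was 11.7-fold lower in KO (log2 -3.55 ± 0.21, SE, n = 3 per group, adjusted p = 1.14e-05), with group means of 8.41 ± 0.10 (SD) in WT and 4.86 ± 0.54 in KO. Elovl3, an elongase of very long chain fatty acids that brown fat induces in the cold, was also lower (-2.0 ± 0.32, adjusted p = 0.0169). Ucp1 was lower too (-0.80 ± 0.14, adjusted p = 0.0257), with group means of 12.53 in WT and 11.73 in KO near the top of the scale, where the highest signal per array was 13.37 to 13.52. Gys2, a glycogen synthase, fell by 3.36 on the log2 scale, the retinol dehydrogenase Dhrs9 fell by 3.02 and Eci3, an enoyl-CoA isomerase of fatty acid oxidation, fell by 2.19. Dcst1, which lies next but 1 to Zbtb7b in the mouse assembly GRCm38.p6, was higher in KO (3.71 ± 0.25, adjusted p = 3.32e-05), from a WT mean of 2.75 at the level of the arrays' medians to 6.46. Dcst2, the gene between them, was lower (-1.97 ± 0.15, adjusted p = 7.71e-05). In total 59 genes were higher and 63 lower in KO at an adjusted p under 0.05, and 2528 at an unadjusted p under 0.05. For all 122 the 3 KO arrays lay on one side of the 3 WT arrays, as did 17.0% of all genes, where chance gives 10%.

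**Figure D1:**
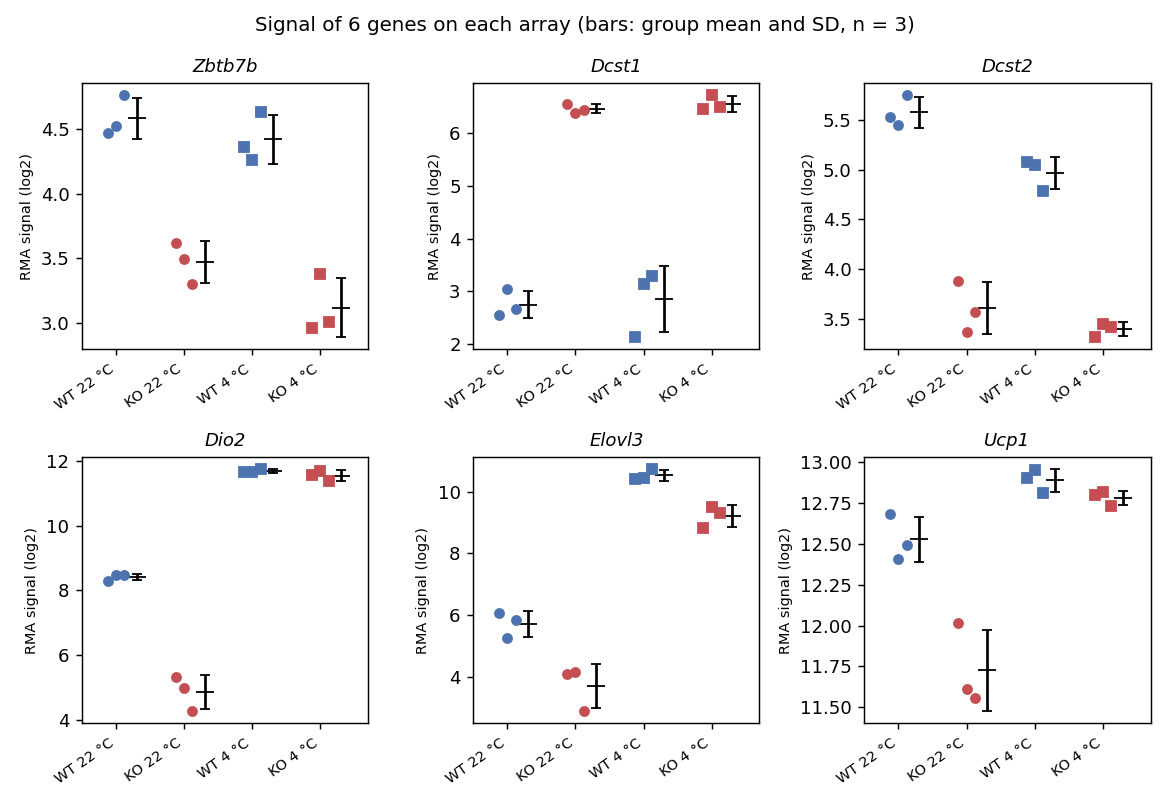
RMA signal (log2, vertical axis) of Zbtb7b, Dcst1, Dcst2, Dio2, Elovl3 and Ucp1 on each of the 12 arrays, by genotype and temperature (horizontal axis), with the group mean and SD (n = 3) beside the points. Dcst1 means were 2.75 and 2.86 in WT against 6.46 and 6.55 in KO, and Dio2 means were 8.41 in WT against 4.86 in KO at room temperature but 11.69 against 11.55 in the cold.

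Among the other genes with the largest differences at room temperature, Cdhr5, a mucin-like cadherin, was higher by 2.32 ± 0.13 (adjusted p = 1.14e-05) and Ptgds, a prostaglandin D synthase, by 2.39 ± 0.30 (adjusted p = 0.00428). Them7 was higher by 2.13 ± 0.17 (adjusted p = 7.71e-05). Prss12 (2.04), Ttpa, the vitamin E transfer protein (1.96), Casp12 (1.82), Gdpd1 (1.70), Fgf13 (1.64) and the sialyltransferase St8sia6 (1.61) were also higher. Speer4d (-2.61), Aldh3b2 (-2.35), the immediate-early nuclear receptor Nr4a3 (-2.27) and Mfsd2a, a lysophospholipid transporter (-1.93), were lower. The genes Ppargc1a (-0.14), Cidea (-0.25), Prdm16 (0.18), Ebf2 (-0.14), Fgf21 (0.08) and Hnrnpu (-0.23) did not pass the test, with adjusted p-values of 0.462 or more.

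By gene lists fixed in advance, the brown adipocyte thermogenic list was lower in KO at room temperature by the list test. Of 21 measured members 0 rose and 3 fell (Dio2, Elovl3 and Ucp1), or 0 and 5 when adjusted over the list alone, with a median of -0.13 (adjusted p = 2.22e-05, and adjusted p = 0.0746 with an estimated correlation). The cAMP and immediate-early list, which shares Dio2, Ucp1 and Ppargc1a, had 3 of 26 members lower (6 adjusted over the list alone) and a median of -0.14 (adjusted p = 0.00161, 0.523 with an estimated correlation). The lipolysis and lipid uptake list had a median of -0.25 over 20 genes with 0 past the test (adjusted p = 0.00161, 0.523 with an estimated correlation), and Lpl, for example, stood at -0.25 ± 0.11 (adjusted p = 0.404). Fatty acid oxidation genes had a median of -0.17 over 22 genes, with 0 past the test and 1 lower when adjusted over the list alone (adjusted p = 0.00877, 0.545 with an estimated correlation, and 0.0822 without KO replicate 2). Nuclear genes of oxidative phosphorylation had a median of -0.05 over 44 genes (adjusted p = 0.0274, 0.523 with an estimated correlation, 0.113 without WT replicate 3 and 0.140 without KO replicate 1). Of the creatine and calcium cycling genes, 1 of 9 rose (2 higher and 1 lower adjusted over the list alone), the creatine kinase Ckb, by 1.35 ± 0.18 (adjusted p = 0.00754), and the list did not pass (adjusted p = 0.283).

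At room temperature 6 further lists passed as higher in KO by the list test and did not pass with an estimated correlation, and of their members 1, in the T cell list, passed on its own. The macrophage list had a median of 0.69 over 17 genes, with 0 past the test over all genes but 11 higher when adjusted over the list alone. Among them were the complement gene C1qb (1.18 ± 0.25) and Cd68 (0.90 ± 0.20; list adjusted p = 7.52e-09, 0.238 with an estimated correlation). The interferon list had a median of 0.59 over 17 genes (0 past the test, 3 adjusted over the list alone; list adjusted p = 4.18e-05, 0.523 with an estimated correlation). Cell cycle genes had a median of 0.27 over 22 genes, with 0 past the test and 1 adjusted over the list alone (adjusted p = 7.83e-05, 0.151 with an estimated correlation). Among genes with a mean signal of at least 5 this list had a median of -0.00291 and did not pass (adjusted p = 0.923), nor did the angiogenesis (0.159) and T cell (0.518) lists. Angiogenesis and hypoxia genes had a median of 0.25 over 15 genes (adjusted p = 0.0149, 0.402 with an estimated correlation). The T cell list had a median of 0.16 over 18 genes, with Cd8a higher by 0.99 ± 0.16 (adjusted p = 0.0208; list adjusted p = 0.0284, 0.523 with an estimated correlation, 0.0556 without WT replicate 2 and 0.218 without KO replicate 2). Cd8a did not pass without WT replicate 1 or 2 or KO replicate 1 or 2 (adjusted p-values of 0.0773, 0.0698, 0.0726 and 0.10). Of the other cell types, neutrophil (median 0.37, adjusted p = 0.447), white adipocyte (0.11, adjusted p = 0.112), B cell (0.17, adjusted p = 0.0572) and endothelial markers (-0.02, adjusted p = 0.767) did not pass. Neither did mural (-0.05, adjusted p = 0.566), Schwann cell (-0.10, adjusted p = 0.687), erythroid (-0.26, adjusted p = 0.616) and hepatocyte markers (-0.12, mean 0.02, adjusted p = 0.616) or extracellular matrix genes (median -0.00374, mean 0.03, adjusted p = 0.931). The skeletal muscle list, a marker of neighbouring tissue in the dissection, differed between arrays of the same group. Its means were 3.19, 6.53 and 2.94 in WT and 8.71, 7.59 and 3.32 in KO, so that the groups overlapped, and 0 of its 21 genes passed (median 2.34, adjusted p = 2.22e-05, 0.562 with an estimated correlation). With that list's mean per array as a covariate, chosen after seeing the data, Dio2, Elovl3 and Ucp1 remained lower (-3.72, -2.09 and -0.83). Mfsd2a (-1.90 ± 0.38, adjusted p = 0.0565), Cd8a (0.91 ± 0.18, adjusted p = 0.0550) and Nr4a3 (-2.43, adjusted p = 0.0568) no longer passed but moved little, from -1.93 ± 0.33, 0.99 ± 0.16 and -2.27. The T cell (median 0.09, adjusted p = 0.370), fatty acid oxidation (-0.12, adjusted p = 0.153) and oxidative phosphorylation lists (-0.02, adjusted p = 0.167) did not pass either.

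The number of genes at room temperature was 65 without WT replicate 1, 50 without KO replicate 2, 63 without KO replicate 3, and 58 for every probe set on its own. It was 37 from the 6 arrays alone, where Elovl3 (adjusted p = 0.101), Ucp1 (0.132), Mfsd2a (0.137) and Cd8a (0.0832) did not pass. Ucp1 did not pass without WT replicate 1 (adjusted p = 0.0950) or 3 (0.0654) or KO replicate 2 (0.113) or 3 (0.102). Elovl3 did not pass without WT replicate 1 (0.0761) or 3 (0.0565), Mfsd2a not without WT replicate 1 (0.0641) or KO replicate 2 (0.110) or 3 (0.0958), Aldh3b2 not without WT replicate 1 (0.0600) and Speer4d not without KO replicate 2 (0.0557). Nr4a3 did not pass in 11 and Fgf13 in 6 of the 12 fits that left out 1 array (up to 0.140 and 0.117). A dimmer second probe set of Dio2, with a mean signal of 2.32, did not show the change (0.94, adjusted p = 0.272).

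The second comparison asked what the knockout changed in the cold. Elovl4, another fatty acid elongase, was lower in KO (-3.57 ± 0.32, SE, n = 3 per group, adjusted p = 3.69e-04), as was Aplnr, the apelin receptor (-2.05 ± 0.24, adjusted p = 0.00276). Eci3 was lower (-2.42 ± 0.23, adjusted p = 5.74e-04), and Gys2, lower by 1.48 (adjusted p = 0.0201), also differed in the same direction as at room temperature. Higher were Dcst1 (3.7 ± 0.25, adjusted p = 5.14e-05), from 2.86 in WT to 6.55 in KO, Cdhr5 (5.68-fold, 2.5 ± 0.13, adjusted p = 5.40e-06) and Aloxe3, a lipoxygenase (1.93 ± 0.16, adjusted p = 1.93e-04). Dio2 (-0.14 ± 0.21, adjusted p = 0.823) and Ucp1 (-0.11 ± 0.14, adjusted p = 0.783) did not differ by the test in the cold, and Elovl3 stood at -1.32 ± 0.32 (adjusted p = 0.0836). In total 80 genes were higher and 122 lower in KO, with 3197 at an unadjusted p under 0.05, and all 202 separated the 3 KO from the 3 WT arrays, as did 20.6% of all genes. After cyclic loess between arrays the split was 107 higher and 103 lower.

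Further genes higher in KO in the cold were Them7 (2.12), Prg4, which encodes lubricin (1.96), Ptgds (1.79), Cacng7 (1.72), the acyl-CoA thioesterase Acot1 (1.70), the oxygen-sensing hydroxylase Egln3 (1.65) and Prss12 (1.63). Lower genes included the immunoglobulin gene Iglv1 (-2.16), Anxa8 (-2.03), Tectb (-1.78), the interferon-inducible GTPase Gbp9 (-1.71), the HSP90 cochaperone Ahsa2 (-1.69), Trim67 (-1.62) and Dcst2 (-1.57). Ppargc1a, a coactivator of mitochondrial and thermogenic genes, stood at 0.54 ± 0.12 (adjusted p = 0.0699). Both temperatures had 14 genes higher in KO, where chance gives 0.213, and 13 lower, where chance gives 0.347. Among the shared genes were Dcst1, Cdhr5, Them7, St8sia6, Ptgds and Got2, which were higher, and Dcst2, Eci3, Gys2, Cish and Zbtb7b, which were lower. A further 2 genes passed in opposite directions, Olfr519 and Tmem82, named after their values were seen.

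The proteasome list was lower in KO in the cold by the list test, with a median of -0.33 over 31 genes, of which 0 rose and 1 fell. Adjusted over the list alone 14 fell (list adjusted p = 3.16e-08, 0.407 with an estimated correlation). Psmc2 was the gene that fell (-0.72 ± 0.15, adjusted p = 0.0495, which did not pass in 11 of 12 fits that left out 1 array). A dimmer second probe set of Psmc2, with a mean signal of 3.32, did not show the change (0.08, adjusted p = 0.924). Psmc4 stood at -0.67 ± 0.16 (adjusted p = 0.0727). The heat shock list had a median of -0.39 over 15 genes, with 0 past the test and 1 higher and 4 lower when adjusted over the list alone (list adjusted p = 0.00191, 0.689 with an estimated correlation). Its mean was 8.92, 9.25 and 8.08 on the KO arrays and 9.39, 9.18 and 9.28 on the WT arrays, so that KO replicate 3 lay apart. The same replicate had a neutrophil list mean of 4.18, against 1.94 to 2.43 on the other cold arrays (list median 0.49, adjusted p = 0.00557, 0.689 with an estimated correlation, and 0.941 without that replicate). Cell cycle genes had a median of -0.23 over 22 genes (0 past the test, 2 lower adjusted over the list alone; list adjusted p = 3.19e-04, 0.190 with an estimated correlation). Among genes with a mean signal of at least 5 the cell cycle (adjusted p = 0.574) and heat shock (0.0842) lists did not pass.

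Of the lists of energy metabolism, 5 passed as lower in KO in the cold by the list test. The tricarboxylic acid cycle list had a median of -0.22 over 21 genes (adjusted p = 0.00339) and the cholesterol synthesis list -0.22 over 19 genes (adjusted p = 0.0123). The branched-chain amino acid list had -0.12 over 18 genes (adjusted p = 0.0104), the glucose uptake and glycolysis list -0.19 over 17 genes (adjusted p = 0.0381) and oxidative phosphorylation -0.06 over 44 genes (adjusted p = 0.0361). With an estimated correlation the adjusted p was 0.689 for each, and among genes with a mean signal of at least 5 none of the 5 passed (0.211, 0.574, 0.324, 0.379 and 0.587). Fatty acid oxidation (median -0.09, adjusted p = 0.236, with 2 higher and 2 lower adjusted over the list alone) and fat synthesis (median -0.02, adjusted p = 0.718) did not pass. None of these 5 lists passed without KO replicate 1, where the adjusted p-values were 0.242, 0.307, 0.415, 0.333 and 0.242. The glucose list also did not pass without WT replicate 3 (0.0858) or KO replicate 2 (0.109), nor oxidative phosphorylation without WT replicate 1 (0.138) or KO replicate 2 (0.101). Within the glucose list the regulator Pfkfb3 was lower (-1.12 ± 0.20, adjusted p = 0.0249) while the transporter Slc2a1 was higher (0.98 ± 0.18, adjusted p = 0.0279). The angiogenesis and hypoxia list had a median of 0.34 over 15 genes, of which 12 lay above 0 and 3 below, 2 passed as higher (Egln3 and Slc2a1) and 4 did so adjusted over the list alone (list adjusted p = 1.86e-04, 0.190 with an estimated correlation). The macrophage list had a median of 0.20, with Mrc1 (1.05 ± 0.20, adjusted p = 0.0328) and Cd68 (0.99 ± 0.20, adjusted p = 0.0466) higher (list adjusted p = 0.0104, 0.689 with an estimated correlation, 0.128 without KO replicate 3 and 0.0607 without WT replicate 1). The interferon list stood at -0.26 (adjusted p = 0.0450, 0.689 with an estimated correlation, and 0.0507 to 0.696 without WT room-temperature replicate 2, WT cold replicate 2 or KO cold replicate 1 or 3, and 0.324 among genes with a mean signal of at least 5). Thermogenic genes did not pass as a list (median -0.06, adjusted p = 0.692). The lipolysis list did not pass either (median -0.06, adjusted p = 0.752), though the lipoprotein receptor Vldlr was higher by 1.18 ± 0.20 (adjusted p = 0.0200).

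In the cold the number of genes was 36, 51 and 85 without WT replicates 1, 2 and 3, 89 without KO replicate 3, and 12 for the 1 KO array left without KO replicates 1 and 3 together (chosen after seeing the data). It was 32 from the 6 arrays alone (where Aplnr had an adjusted p of 0.0568), 75 for every probe set, 397 for genes with a mean signal of at least 5 and 307 with array weights. Of the 20 genes with the largest differences, 9 did not pass in every fit that left out 1 array (Acot1, Ahsa2, Anxa8, Egln3, Iglv1, Prg4, Prss12, Ptgds and Trim67, with adjusted p-values of up to 0.113, 0.0885, 0.0751, 0.0953, 0.176, 0.0593, 0.0953, 0.0888 and 0.0681), each of them without WT replicate 1. Neither did Pfkfb3 (up to 0.111), Slc2a1 (0.111), Mrc1 (0.134), Cd68 (0.192) or Vldlr (0.0916).

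Over both temperatures, 176 genes were higher and 185 lower in KO, at 6 arrays against 6. Dcst1 (3.7 ± 0.18, adjusted p = 8.83e-07), Cdhr5 (2.41 ± 0.09, adjusted p = 1.40e-07), Them7 (2.12 ± 0.12, adjusted p = 2.91e-06) and St8sia6 (1.5 ± 0.10, adjusted p = 1.53e-05) were higher. Eci3 (-2.31 ± 0.16, adjusted p = 1.98e-05), Gys2 (-2.42 ± 0.18, adjusted p = 3.94e-05), Elovl4 (-2.15 ± 0.22, adjusted p = 6.07e-04) and Elovl3 (-1.66 ± 0.23, adjusted p = 0.00391) were lower. Abra (2.43), Crtac1 (1.92), Sorcs2 (1.78) and Hpd (1.46) were among the other higher genes, and Igkv4-91 (-2.41), Anxa8 (-1.94) and Aldh3b2 (-1.67) among the lower ones. Ckb (1.00 ± 0.13, adjusted p = 0.00308) and the creatine transporter Slc6a8 (0.77 ± 0.15, adjusted p = 0.0276) rose. The creatine and calcium cycling list did not pass as a whole (median 0.01, adjusted p = 0.450). Macrophage genes had a median of 0.43 over 17 genes, of which 3 rose (Cd68, Mrc1 and Itgam) and 7 adjusted over the list alone (list adjusted p = 2.75e-08, 0.273 with an estimated correlation). Angiogenesis and hypoxia genes had a median of 0.27, with 3 of 15 higher (list adjusted p = 4.79e-05, 0.198 with an estimated correlation). Thermogenic genes had a median of -0.16 with 3 of 21 lower (list adjusted p = 0.00400, 0.256 with an estimated correlation and 0.146 among genes with a mean signal of at least 5), of which Ucp1 (-0.46 ± 0.10, adjusted p = 0.0401) did not pass in 11 of 12 fits that left out 1 array (up to 0.104). The proteasome list had a median of -0.17 (adjusted p = 1.56e-05, 0.552 with an estimated correlation) with 0 of 31 genes past the test.

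The averaged count of 361 genes moved to 199 and 206 without WT room-temperature replicates 1 and 3, to 227 without KO room-temperature replicate 2, and to 162, 197 and 185 without WT cold replicates 1, 2 and 3. It was 231 with the skeletal muscle covariate, 171 with 1 KO cold array left (without replicates 1 and 3), 234 for every probe set and 613 for genes with a mean signal of at least 5. Abra, Igkv4-91 and Sorcs2 did not pass in 5, 10 and 9 of the 12 fits that left out 1 array (adjusted p-values of up to 0.0607, 0.124 and 0.0873), nor did Mrc1, Itgam and Slc6a8 in 7, 10 and 7 (up to 0.0692, 0.110 and 0.0751).

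The third comparison asked what differed in WT brown fat between 4 h of cold and room temperature. The labels gave no hour of collection, so an effect of the hour cannot be told apart from cold in any such comparison. Mfsd2a rose 51.4-fold (5.68 ± 0.33, SE, n = 3 per group, adjusted p = 2.02e-06), Elovl3 28.0-fold (4.81 ± 0.32, adjusted p = 5.30e-06), Dio2 9.70-fold (3.28 ± 0.21, adjusted p = 4.46e-06) and Ppargc1a 5.0-fold (2.32 ± 0.12, adjusted p = 1.12e-06). The heme-degrading enzyme Hmox1 rose by 4.94 ± 0.43 (adjusted p = 2.72e-05), the clock transcription factor Arntl by 4.76 ± 0.43 (adjusted p = 3.47e-05), the tight junction gene Cldn1 by 4.73 and Dhrs9 by 4.68. Hcar1, the lactate receptor, fell by 3.64 on the log2 scale (adjusted p = 4.96e-05), the chloride channel Ano1 fell by 3.08, the endothelial ligand Angpt1 fell by 3.02 and Aplnr fell by 2.62. Ucp1, already near the top of the scale, stood at 0.36 ± 0.14 (adjusted p = 0.101). Fgf21 rose by 1.23 ± 0.26 (adjusted p = 0.00562) and Hnrnpu by 0.75 ± 0.12 (adjusted p = 0.00111), and Ebf2 stood at -0.97 ± 0.14 (adjusted p = 6.64e-04). In total 2082 genes rose and 1770 fell, of which 3833 of 3852 separated the cold from the room-temperature arrays, as did 36.8% of all genes. The balance turned with the scaling, to 1753 higher and 2078 lower after cyclic loess and to 1730 and 1956 with each array centred on its median.

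The KO tissue was asked the same question. Dhrs9 (7.25 ± 0.33, adjusted p = 1.47e-07), Mfsd2a (6.43 ± 0.33, adjusted p = 4.77e-07) and Elovl3 (5.49 ± 0.32, adjusted p = 1.27e-06) rose. Dio2 rose 103-fold (6.69 ± 0.21, adjusted p = 1.26e-08) and Ppargc1a 8.0-fold (3.0 ± 0.12, adjusted p = 9.00e-08). Ucp1 rose by 1.06 ± 0.14 (adjusted p = 2.80e-04), from 11.73 to 12.78 in group means, against 12.53 and 12.89 in WT. Cldn1 (5.07), Lrrc52 (4.74), Arntl (4.67), Tmem82 (4.64), the placental growth factor Pgf (4.39) and Nr4a3 (4.33) rose as well. Leptin (Lep) fell by 5.30 on the log2 scale (adjusted p = 7.74e-05), Aplnr fell by 4.63 (adjusted p = 4.77e-07), the death ligand Tnfsf10 fell by 3.61 and Angpt1 fell by 3.37. In total 1849 genes rose and 2405 fell, and 4144 of these 4254 separated the groups, as did 31.6% of all genes. When each array was centred on its median, the median of all genes in this comparison moved to -0.12 and the split to 1342 higher and 3218 lower. The count was 2737 from the 6 arrays alone and between 3200 and 4320 when 1 array was left out.

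Both genotypes shared 1256 genes that rose in the cold, where chance gives 174, and 1241 that fell, where chance gives 192, while 5 genes passed in opposite directions. Over both genotypes 2859 genes rose and 3165 fell, or 2271 and 4036 when each array was centred on its median, and 3484 changed by at least 1.5-fold. Mfsd2a (6.06 ± 0.23, adjusted p = 1.82e-08), Dhrs9 (5.97 ± 0.23, adjusted p = 1.82e-08), Elovl3 (5.15 ± 0.23, adjusted p = 5.44e-08), Dio2 (4.98 ± 0.15, adjusted p = 2.51e-09) and Acot5 (3.65 ± 0.20, adjusted p = 2.45e-07) rose. Lep (-3.77 ± 0.40, adjusted p = 2.44e-05), Aplnr (-3.63 ± 0.17, adjusted p = 7.38e-08), Rasl12 (-2.68 ± 0.11, adjusted p = 3.08e-08) and the clock gene Per3 (-2.52 ± 0.12, adjusted p = 9.11e-08) fell. The 20 genes with the largest changes passed in every fit that left out 1 array, in WT, in KO and over both.

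**Figure D2:**
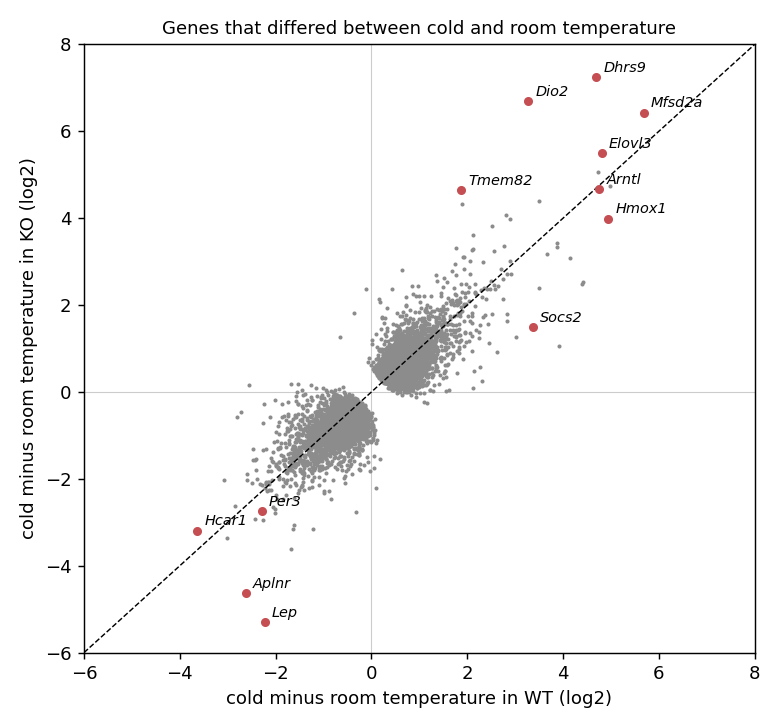
Cold minus room temperature difference (log2) in WT (horizontal axis) and in KO (vertical axis) for the 6024 genes that differed with temperature over both genotypes, with the line of equal response dashed and 12 genes named. Dio2, with 3.28 in WT and 6.69 in KO, and Tmem82, with 1.86 in WT and 4.64 in KO, lie above the line, and Socs2, with 3.36 in WT and 1.49 in KO, lies below it.

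Heat shock genes rose in the cold over both genotypes. Of 15 measured members 14 rose and 1 fell, with a median of 1.51 (list adjusted p = 1.58e-09, 0.535 with an estimated correlation), and the cochaperone Bag3 (1.65), Hsp90aa1 (2.40) and Hsph1 (3.42) are examples. In WT the median was 1.82 and in KO 1.16, and Hspa1a was 10.92, 11.82 and 7.78 on the 3 KO cold arrays. Genes of endoplasmic reticulum stress and the ATF4 pathway rose in 15 and fell in 4 of 23 members (median 0.62, list adjusted p = 8.49e-04, 0.535 with an estimated correlation), with Atf4 up by 1.69 and Dnajb9 by 1.19. Proteasome genes rose in 14 and fell in 1 of 31 (median 0.26, list adjusted p = 8.49e-04, 0.535 with an estimated correlation). The cAMP and immediate-early list had 14 members that rose and 4 that fell of 26 (median 0.48, list adjusted p = 8.49e-04, 0.535 with an estimated correlation), among them Nr4a3 (3.11) and Crem (1.03). Among genes with a mean signal of at least 5 the heat shock list held, whereas the stress (adjusted p = 0.0698), proteasome (0.0521) and cAMP (0.0698) lists did not pass.

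Thermogenic genes went both ways in the cold. Dio2, Elovl3, Ppargc1a (2.66 ± 0.09) and Ucp1 (0.71 ± 0.10, adjusted p = 1.69e-04) were among 7 that rose, and Ebf2 (-0.70 ± 0.10, adjusted p = 2.45e-04) was among 6 that fell of 21. The list did not pass by camera (median -0.05, mean 0.53, adjusted p = 0.427). By fry it passed as higher in WT (adjusted p = 0.00338) and in KO (adjusted p = 1.68e-05). Prdm16 (-0.45 ± 0.15, adjusted p = 0.0409) did not pass in 10 of 12 fits that left out 1 array (up to 0.0928), and Cidea did not pass (-0.23 ± 0.09, adjusted p = 0.0647). The dim second probe sets of Ebf2 (0.06) and Gdf5 and a second probe set of Hnrnpu (0.18 against 0.85 ± 0.08 for the brighter one) did not show the changes of the brighter ones. Angiogenesis and hypoxia genes rose in 8 and fell in 4 of 15 (median 0.35, list adjusted p = 0.0137, 0.535 with an estimated correlation), with Hmox1 at 4.47 and the vasoconstrictor Edn1 at 1.98. In the glucose uptake and glycolysis list 6 of 17 rose, including Pfkp (1.51) and Slc2a1 (1.23), and the insulin-dependent transporter Slc2a4 fell by 0.64 (median 0.19, list adjusted p = 0.0201, 0.535 with an estimated correlation). Neither of these 2 lists passed among genes with a mean signal of at least 5 (0.382 and 0.158).

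Fat synthesis genes fell in the cold, 13 of 21 against 2 that rose (median -0.81, list adjusted p = 1.24e-04, 0.535 with an estimated correlation). Srebf1, a transcription factor of lipogenesis, stood at -2.14, the acetyl-CoA carboxylase Acaca at -1.88 and Dgat2 at -1.24, whereas Gpam rose by 0.76 in WT and 0.56 in KO. Branched-chain amino acid breakdown fell in 11 of 18 members (median -0.47, list adjusted p = 9.52e-05, 0.535 with an estimated correlation), with Hibch at -0.90. The tricarboxylic acid cycle had 8 of 21 members lower (median -0.18, list adjusted p = 0.00562, 0.608 with an estimated correlation). Fatty acid oxidation had 8 of 22 lower (median -0.20, list adjusted p = 0.0222, 0.654 with an estimated correlation) and oxidative phosphorylation 7 of 44 with 1 higher (median -0.15, list adjusted p = 0.0117, 0.535 with an estimated correlation). Among genes with a mean signal of at least 5 these last 3 lists did not pass (0.0616, 0.106 and 0.0698). Fatty acid oxidation no longer passed without KO room-temperature replicate 3 or KO cold replicate 1, or with the skeletal muscle covariate. Cholesterol synthesis went both ways, with 3 higher and 6 lower of 19 (adjusted p = 0.427). Lipolysis and lipid uptake did as well, with 4 higher and 6 lower of 20 (adjusted p = 0.923), where Abhd5, an activator of lipolysis, rose by 0.97 ± 0.09 and Plin2, a lipid droplet coat protein, by 1.30.

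Clock genes were split in the cold, with 7 of 16 higher and 7 lower (adjusted p = 0.916). Arntl (4.71), Npas2 (2.25) and Clock (1.31) rose, whereas Per3, Dbp (-2.21), Tef (-1.07) and Hlf (-0.91) fell, in both genotypes and with 0 of 16 genes different between genotypes at either temperature. The labels gave no hour of collection.

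Macrophage genes rose in the cold in 8 and fell in 1 of 17 (median 0.27, list adjusted p = 0.00887, 0.545 with an estimated correlation and 0.0988 among genes with a mean signal of at least 5), with Lyve1 up by 1.80 and Cd163 by 0.83. The other cell type lists, except skeletal muscle, did not pass over both genotypes. Of the vessels and nerves these were endothelial (5 higher and 5 lower of 14, adjusted p = 0.923), mural and smooth muscle (1 and 5 of 12, adjusted p = 0.0828) and Schwann cell and nerve genes (0 and 3 of 9, adjusted p = 0.154). Of blood cells these were B cell (0 and 2 of 13, adjusted p = 0.196), T cell (3 and 0 of 18, adjusted p = 0.241), neutrophil (0 of 13, adjusted p = 0.337) and erythroid genes (0 of the 3 measured, adjusted p = 0.923). The rest were white adipocyte (3 and 1 of 15, adjusted p = 0.729), extracellular matrix (3 and 0 of 19, adjusted p = 0.510) and hepatocyte genes (1 of 19, Hpx, up by 2.31, adjusted p = 0.753). Interferon genes went both ways (3 and 3 of 17, adjusted p = 0.923), as did cell cycle genes (3 and 1 of 22, adjusted p = 0.753). Creatine and calcium cycling genes did so too (2 and 3 of 9, adjusted p = 0.923), where Atp2a2, the calcium pump, rose by 1.02 and Ckb by 0.48. The skeletal muscle list had a median of 1.63 with 0 of 21 past the test (adjusted p = 0.0201, 0.843 with an estimated correlation), a result that ended without any 1 of 6 of the 12 arrays and among genes with a mean signal of at least 5 (0.170). In WT alone the cell cycle list (median 0.29, 4 of 22 higher, adjusted p = 0.00415, 0.449 with an estimated correlation) passed. So did the T cell list there (median 0.31, 3 of 18 higher, adjusted p = 0.0162, 0.594 with an estimated correlation and 0.112 without WT cold replicate 2). Among genes with a mean signal of at least 5 neither passed (0.611 and 0.828).

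**Figure D3:**
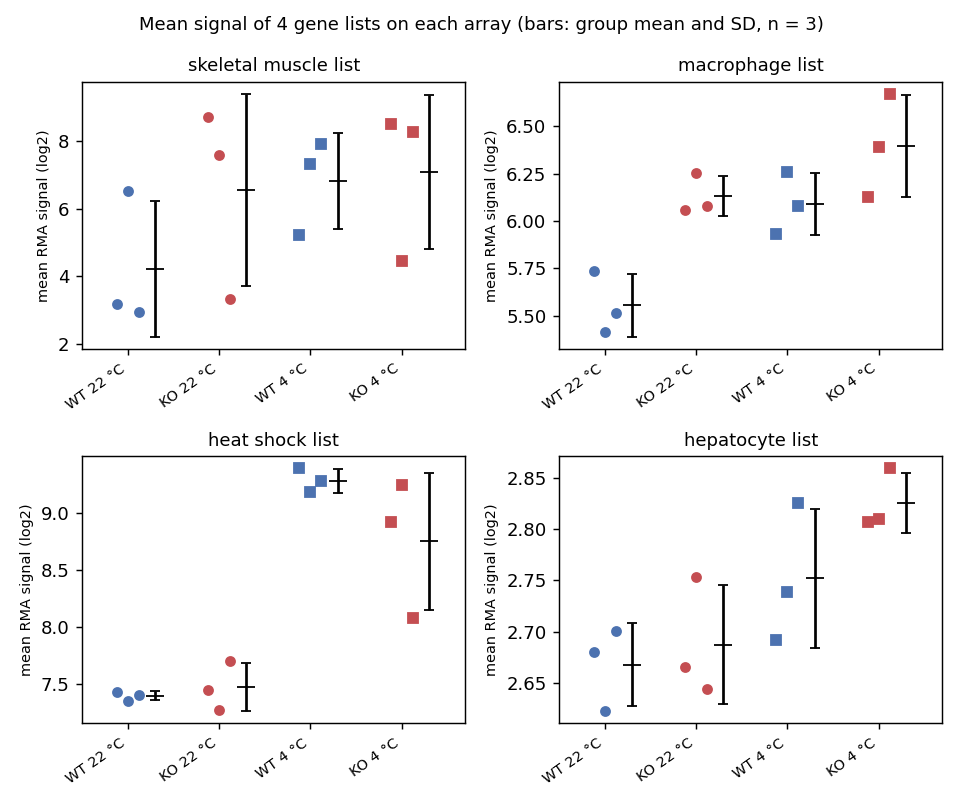
Mean RMA signal (log2, vertical axis) of the skeletal muscle, macrophage, heat shock and hepatocyte lists on each of the 12 arrays, by genotype and temperature (horizontal axis), with the group mean and SD (n = 3) beside the points. Skeletal muscle means ranged from 2.94 to 8.71 within and across groups, and hepatocyte means from 2.62 to 2.86.

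The last comparison asked whether the cold response differed between the genotypes. Dio2 rose by 3.41 ± 0.30 more in KO on the log2 scale (SE, adjusted p = 0.00190), from a lower starting level to a like level in the cold. Tmem82 (2.78 ± 0.33, adjusted p = 0.0135), Aloxe3 (2.18 ± 0.22, adjusted p = 0.00475) and Adam12, a metalloprotease (1.17 ± 0.17, adjusted p = 0.0453), also rose more in KO, and Socs2, a suppressor of cytokine signalling, rose less (-1.87 ± 0.25, adjusted p = 0.0301). With Olfr519 (1.93, adjusted p = 0.00483), 5 genes had a higher and 1 a lower response in KO, and 2324 genes had an unadjusted p under 0.05. Several genes that passed at 1 or both temperatures did not pass this test, among them Tectb (-1.67, adjusted p = 0.0511), Elovl4 (-2.84, adjusted p = 0.0570), Aplnr (-2.01, adjusted p = 0.0622), and Gbp9 (-1.92, adjusted p = 0.0695). Nor did Dhrs9 (2.56, adjusted p = 0.0766), Gys2 (1.88, adjusted p = 0.102), Ucp1 (0.69 ± 0.20, adjusted p = 0.282) and Elovl3 (0.69 ± 0.45, adjusted p = 0.619).

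By lists, the cold response of cell cycle genes differed, with a median of -0.54 over 22 genes, where 0 passed the test and 6 were lower when adjusted over the list alone, such as Mki67 (-1.36 ± 0.28) and Cdk1 (-1.08 ± 0.24; list adjusted p = 1.40e-08). Their cold median was 0.29 in WT (4 rose and 0 fell) and -0.20 in KO (1 rose and 3 fell, list adjusted p = 0.0730). At room temperature they were higher in KO by the list test, but not with an estimated correlation (adjusted p = 0.151). Among genes with a mean signal of at least 5 they did not pass there either (adjusted p = 0.923). The interaction call of the cell cycle list was the 1 list call in any comparison that held with an estimated correlation (adjusted p = 0.0411). The genes of this list were dim, with list means of 3.26 to 3.77 per array, and the interaction did not pass among genes with a mean signal of at least 5 (adjusted p = 0.695). The cAMP list had a larger response in KO by the list test, with 1 of 26 genes past the test (median 0.38, adjusted p = 1.59e-05, 0.577 with an estimated correlation). That gene, Dio2, is shared with the thermogenic list. The cold median of the cAMP list was 0.38 in WT (adjusted p = 0.0336, 0.599 with an estimated correlation and 0.571 among genes with a mean signal of at least 5). In KO it was 0.50 (adjusted p = 2.02e-05, 0.487 with an estimated correlation). The thermogenic list also had a positive difference (median 0.26, adjusted p = 0.00194, 0.185 with an estimated correlation). With cold this list did not pass by camera in WT (median -0.09, mean 0.35, adjusted p = 0.655) or in KO (median -0.03, mean 0.71, adjusted p = 0.132). By fry it passed as higher in WT (adjusted p = 0.00338) and in KO (adjusted p = 1.68e-05). At room temperature it was lower in KO by the list test (adjusted p = 2.22e-05), but not with an estimated correlation (adjusted p = 0.0746). The proteasome (-0.25, adjusted p = 7.37e-05, 0.577 with an estimated correlation) and heat shock lists (-0.59, adjusted p = 0.00143, 0.614 with an estimated correlation) had lower responses in KO by the list test, with 0 genes past the test. Their medians were 0.39 in WT and 0.15 in KO (adjusted p = 0.181), and 1.82 and 1.16. The interferon list (-0.86, adjusted p = 7.32e-06, 0.577 with an estimated correlation) went in opposite directions, at 0.45 in WT (adjusted p = 0.0535) and -0.29 in KO (adjusted p = 0.122), neither of which passed. Over the 6024 genes that changed with cold, the signed difference in response had a median of 0.04 (fry p = 0.339, exact permutation p = 0.320 over 400 relabelings, two-sided), and 45.5% of the genes responded less in KO. Signed in this way, the median was -0.04 over the 2859 that rose (53.4% responded less in KO) and 0.11 over the 3165 that fell (38.3%). Without the sign, both sets shifted toward a lower cold minus room temperature difference in KO. An offset between arrays cannot be told apart from a response difference here. The median interaction of all genes was -0.0114, and -0.0856 with each array centred on its median.

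The 6 interaction genes became 3 without any 1 of the WT cold replicates, 11 without KO room-temperature replicate 1, and 20 and 12 without KO cold replicates 1 and 3 in turn. There were 3 with the mean of a gene's probe sets or with every probe set, 26 for genes with a mean signal of at least 5, 17 (5 higher and 12 lower) with arrays centred on their medians, 19 with a trended and robust spread, 22 with array weights and 12 with the skeletal muscle covariate. Adam12, Socs2 and Tmem82 did not pass in 10, 7 and 4 of the 12 fits that left out 1 array (up to 0.135, 0.123 and 0.0580), and Dio2 did not pass with the mean of its 2 probe sets (1.04, adjusted p = 0.219). Without KO cold replicates 1 and 3 together these values rest on 1 KO cold array. There the heat shock (0.389) and proteasome (0.0852) lists did not pass, while the signed median was 0.11 and passed by fry.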

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

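The counts of other splits were set beforehand, while every test of an explanation, the skeletal muscle covariate and the description of the highest relabeling were chosen only after the result was seen.

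The response to cold differed between WT and KO mice for 6 genes by the interaction test. On the log2 scale the response was higher in KO by 3.41 for Dio2, 2.78 for Tmem82, 2.18 for Aloxe3, 1.93 for Olfr519 and 1.17 for Adam12, and for Socs2 the difference was -1.87. Dio2, Tmem82 and Adam12 began lower in KO at room temperature, at -3.55, -1.27 and -1.33 against WT, whereas Aloxe3 (-0.25, adjusted p = 0.612) and Socs2 (0.67, adjusted p = 0.132) did not differ there by the test and stood apart in the cold (1.93 and -1.20). Of 100 relabelings, 3 gave at least the 6 genes of the real labels, the real one included. Relabelled groups mix WT and KO arrays, so genotype differences add to their spread and can lower their counts. This share therefore does not exclude chance. The highest other relabeling called 68. That relabeling put the 3 arrays with the highest skeletal muscle mean at each temperature on 1 side, and 19 of its 68 genes were among the 21 of the muscle list, so muscle signal that differs within groups is a structure of these arrays. Adam12 (1.15, adjusted p = 0.0620) did not pass with the skeletal muscle covariate.

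Several gene lists also differed between the genotypes in their response to cold by the interaction test. The median difference was 0.26 for thermogenic genes and 0.38 for cAMP and immediate-early genes, and it was -0.59 for heat shock, -0.25 for the proteasome, -0.86 for interferon response and -0.54 for cell cycle genes. With an estimated correlation only the cell cycle list of these 6 passed (adjusted p = 0.0411), against 0.185, 0.577, 0.614, 0.577 and 0.577 for the others in that order. It was -0.29 for white adipocyte genes (adjusted p = 0.0219, 0.577 with an estimated correlation, and 0.0527 to 0.183 without WT room-temperature replicate 2 or 3, KO room-temperature replicate 2, WT cold replicate 2 or KO cold replicate 2). For T cell genes it was -0.36 (adjusted p = 0.00739, 0.614 with an estimated correlation, 0.0757 without WT cold replicate 2 and 0.0844 without KO cold replicate 2). For skeletal muscle genes it was -2.38 (adjusted p = 0.0106, 0.730 with an estimated correlation), and this result ended without WT room-temperature replicate 1 or 3, KO room-temperature replicate 1 or 2, WT cold replicate 2 or 3 or KO cold replicate 2 (0.0527 to 0.450).

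Thermogenic Dio2, Elovl3 and Ucp1 were lower in KO at room temperature, and a larger share of skeletal muscle RNA in the KO dissections could have lowered them. With the muscle list as a covariate they stood at -3.72, -2.09 and -0.83 and all passed (adjusted p-values of 3.06e-05, 0.0329 and 0.0490), with a median ratio of 1.05 to the change without it, which argues against that source. A clock phase that differed between the genotypes stays open, since the clock score of KO minus WT was -0.0830 of the cold response, with a 95% interval of -0.259 to 0.0926. A lower cold-type stimulation of the KO tissue as a whole would lower the 2859 genes that rise in the cold. At room temperature they showed no shift as a set, with a median of -0.00353, 50.9% below 0 and a fry p of 0.846. Of the 63 genes lower in KO there, 16 rose and 27 fell with cold in WT. Both comparisons use the same WT room-temperature arrays, so genes by chance high on them lean toward a fall with cold. These counts therefore decide nothing here. The set of 2859 genes thus does not show a lower stimulation of the tissue as a whole. A small one, or one limited to some of these genes, stays open. An effect of the Zbtb7b loss on these genes, direct or indirect, is a biological explanation that was not tested.

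Probe sets without a single gene symbol were in no comparison of genes. Of these 17824 probe sets, 1656 were higher in the cold over both genotypes (9.29%), 870 were lower, and 58 differed between the genotypes.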

How the results depend on the processing

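The skeletal muscle covariate and leaving out KO cold replicates 1 and 3 together were chosen only after the result was seen. The latter leaves 1 KO cold array, assumed to vary like the other groups, so calls gained or lost there rest on 1 array. No called gene named in the text turned its sign for the probe set used, and no called list passed in the opposite direction. Dim second probe sets turned without passing for Dio2 (0.94 for genotype at room temperature, 0.27 over both, -0.70 for cold in KO, -0.03 over both, -1.34 for the interaction), Ebf2 (0.06 for cold over both) and Slc2a1 (-0.25 for cold in WT). That of Psmc2 did so too (0.08 for genotype in the cold). The cause of the changes below was not tested. The cell cycle list at room temperature turned from 0.27 to -0.00291 among genes with a mean signal of at least 5 and did not pass. With the muscle covariate, which by construction takes out its mean, the muscle list test turned down without passing for genotype at room temperature (-0.0469) and over both (0.00936) and for cold over both (0.107). Without KO cold replicates 1 and 3 it turned down over both (0.00923, not passed), and passed as lower for genotype in the cold (-2.30) and cold in KO (-2.08), where it had not passed before. Asking for a 1.5-fold change left 3484 genes in the averaged cold comparison. From the 6 arrays of a comparison alone the counts fell to 37 for genotype at room temperature, 32 for genotype in the cold and 2737 for cold in KO, and rose to 4442 for cold in WT. With every probe set they fell to 58 for genotype at room temperature, 75 in the cold, 234 over both and 3 for the interaction, and rose to 4591 for cold in WT, 4844 in KO and 8089 over both. Among genes with a mean signal of at least 5 they were 167 for genotype at room temperature, 397 in the cold, 613 over both, 26 for the interaction, and 3691, 3856 and 4974 for cold in WT, in KO and over both, and Zbtb7b fell below that signal and has no value there. Array weights gave 307 for genotype in the cold and 22 for the interaction, and the interaction count was 3 with mean probe sets, 17 with centred arrays and 19 with a trended and robust spread. With the muscle covariate the averaged genotype count was 231, of which 209 were among the 361, the interaction count was 12 and the signed cold response difference was -0.0176 and did not pass. Without KO cold replicates 1 and 3 the genotype counts were 12 in the cold, 10 of them among the 202, and 171 over both, the signed difference was 0.11 and passed, and Zbtb7b in the cold stood at -1.04 (adjusted p = 0.129).

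Leaving out 1 array at a time gave 50 to 164 genes for genotype at room temperature, 36 to 289 in the cold and 162 to 488 over both. It gave 2676 to 4308 for cold in WT, 3200 to 4320 in KO and 5220 to 6099 over both, and 3 to 20 for the interaction. The signed difference ranged from 0.0159 to 0.0978, and the highest came without KO cold replicate 3, where it passed by fry. Genes higher in the cold in both genotypes numbered 942 to 1351 and lower ones 936 to 1298. The Zbtb7b difference ranged from -1.18 to -1.02 at room temperature, -1.43 to -1.19 in the cold and -1.27 to -1.15 over both, and passed each time. The arrays without which a count moved by over 1.5 times are named with the comparison they belong to.

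With the replicate number as a block the counts were 91, 140 and 266 for genotype at room temperature, in the cold and over both, of which 83, 127 and 241 were shared with the fit without it. They were 3660, 4072 and 5884 for cold in WT, in KO and over both (3507, 3926 and 5688 shared) and 7 for the interaction (4 shared). After group means were removed, arrays with the same number correlated across genes at a mean r of -0.0658, with a range of -0.537 to 0.451 over 18 pairs. The mean for other numbers, 0.0322, is tied to this one, because the deviations within a group sum to 0. Whether the numbers pair the arrays therefore stays open.

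Of the 78 list calls, 75 held with array weights, 75 with centred arrays, 71 with cyclic loess, 59 with the muscle covariate, 41 with fry and 1 with an estimated correlation, and 33 of the 76 that could be tested held among genes with a mean signal of at least 5. Of the 424 calls of named genes, 413 held with array weights, 403 with centred arrays, 394 with the block, 387 with the muscle covariate and 329 without KO cold replicates 1 and 3. All 341 that could be tested held among brighter genes. That setting leaves each difference unchanged and adjusts over 8475 instead of 22180 genes, so few calls could end there. A dim signal limits what can be seen for Zbtb7b and the cell cycle genes. It also limits the T cell, B cell, neutrophil and erythroid lists, both where they passed and where they did not. Their means per array were 2.74 to 3.52, 2.43 to 2.91, 1.94 to 4.18 and 2.18 to 2.80.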

Other observations

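The counts of other splits were set beforehand, and the tests of the clock genes and of the genes beside Zbtb7b were chosen only after the result was seen.

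Genes of blood vessels changed in the cold without moving 1 way as a class. Over both genotypes the endothelial genes Pecam1 (0.65 ± 0.09, adjusted p = 2.04e-04) and Sox18 (1.11 ± 0.15, adjusted p = 1.40e-04) rose, while the angiopoietin receptor Tek (-0.96 ± 0.13, adjusted p = 1.85e-04) and its partner Tie1 (-0.68 ± 0.09, adjusted p = 1.47e-04) fell. Of the genes in the mural list, Cspg4 (-1.5 ± 0.12, adjusted p = 2.21e-06), Notch3 (-1.02 ± 0.15, adjusted p = 2.76e-04) and the smooth muscle myosin Myh11 (-0.98 ± 0.10, adjusted p = 2.11e-05) fell, whereas Cnn1 rose by 1.45 ± 0.23 (adjusted p = 4.72e-04). In whole tissue a change within cells cannot be told apart from a changed share of them. None of these 8 genes differed in its response between the genotypes by the test.

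The white adipocyte list did not pass in the cold over both genotypes (3 higher and 1 lower of 15, adjusted p = 0.729). Of its genes Npr3, a receptor that clears natriuretic peptides (1.76 ± 0.21, adjusted p = 4.53e-05), and Nnmt, a methyltransferase (1.67 ± 0.24, adjusted p = 1.94e-04), rose, while Lep fell by 3.77 on the log2 scale (adjusted p = 2.44e-05). Got2, the mitochondrial aspartate aminotransferase, was higher in KO at room temperature (1.13 ± 0.13, adjusted p = 0.00155) and in the cold (0.80 ± 0.13, adjusted p = 0.0140). Cish, a suppressor of cytokine signalling, was lower at both (-1.19 ± 0.17, adjusted p = 0.00868, and -0.90 ± 0.17, adjusted p = 0.0287). Got2 and Cish were chosen after their values were seen.

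Genes beside Zbtb7b differed between the genotypes, namely Dcst1 (3.7), Dcst2 (-1.77) and Flad1 (-0.43 ± 0.08, adjusted p = 0.0253 over both temperatures). They were 3 of the 20 nearest genes, but Dcst1 and Dcst2 prompted the test. Without these 2, 1 of the other 18 differed, as many as in 24.7% of 21709 windows of those places. An effect of the modified locus on its nearest genes, such as a changed transcript across them, therefore stays open and cannot be told apart from other causes. A wide stretch of another strain's chromosome around the locus stays open, since 4 of the 180 genes at places 11 to 100 on each side differed, where the median window had 3 and 33.2% of windows had as many. No biological explanation by the loss of the protein was tested for these genes.

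The clock genes that differ between cold and room temperature could reflect another hour of collection. Of 15 genes, 12 followed the pattern of a shifted clock, with all 5 RORE-driven genes higher and 7 of 10 E-box or D-box genes lower, while Per1 (0.47) and Ciart (1.00) rose and Nr1d2 did not pass. Cold and the hour cannot be told apart, because the labels give no hour and every cold array would share it, and a response of the clock to cold was not tested apart from it. The same limit holds for every gene and list in the comparisons of cold with room temperature.

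For the comparisons of 3 against 3 arrays, 10 splits are too few for a share under 0.05. The real split, the 1 of 10 with as many genes, called 122 for genotype at room temperature, 202 in the cold, 3852 for cold in WT and 4254 for cold in KO, and the highest other split called 0 in each. Over both temperatures the 361 genes of the genotype comparison were reached by 1 of 100 relabelings, the real one, with 68 as the highest other. Over both genotypes the 6024 genes of the cold comparison were likewise reached by 1 of 100, with 642 as the highest other. A share of 1 of 100 is the lowest these relabelings can give, so chance was unlikely for both but not excluded. Relabelled groups mix arrays of the real groups, so real differences add to their spread and can lower their counts. This also holds for the splits of 3 against 3, so the gap to the other counts is no measure of chance.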
